A study of Drosophila melanogaster and Mus musculus with 18 samples.

How the data were processed

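DNA captured with roX2 from S2 cells was sequenced by the authors, along with input libraries and Xist captures from mouse fibroblasts. Per the labels' protocols, S2 cells were grown at 27 °C, fixed with 1% formaldehyde for 10 min and again as nuclei with 3% for 45 min, and captured DNA was sheared to about 300 bp. The submitters' processing notes name cutadapt, Bowtie2, SAMtools and MACS2, and the builds dm6, mm10 and GRCm38, without versions or roles. The thresholds, the caller of the domains and the method behind the changed regions are not given in the sources used here. A name given to the changed-region lists mentions a z score of 10 and a fold change, but the lists hold neither, so no size of change can be given.

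The deposited lists hold positions, and 4 of the 5 have no value per entry. The CO1 domain list has 2 values per domain, each a score deposited by the authors with no stated scale; the second never exceeded the number of 250 bp bins in any of the 429 domains. These scores served only to rank or describe domains within that list. Changed regions lie on a 100 bp grid and CO1 domains on a 250 bp grid. The 714 summit entries have the same start and end, so the coordinate convention leaves a listed position uncertain by 1 bp. How closely a summit locates roX2, on DNA sheared to about 300 bp, is not given. The labels tie the CES summits to the 2 heat shock mock libraries, the autosomal summits to the 3 heat shock libraries and the changed regions to all 5. Lists were not kept apart by replicate, so a pooled call that rests on a single library cannot be recognised, and no test here measures replicate spread. Reads mapped to repeats or lost to mappability would change which sites appear, and neither can be checked from positions.

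Gene positions came from a RefSeq table for Release 6, the assembly named dm6, with 17872 genes, 17684 of them on the 6 arms. It has no strand, exons or sequence in the form used here. Arm length was taken as the last annotated gene end or listed position. The 1 heat shock summit on the mitochondrial genome, and 5 CO1 domains on Y and the mitochondrial genome, were left out of arm tests.

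The expected count for an overlap came from 10000 random placements of the same number of sites on the same arm, over gene bodies plus 1 kb, with a two-sided permutation p whose smallest value is 0.0002. Annotation classes were set against uniform placement on the arm instead. Regions entered gene-list and annotation tests by their midpoint, and a list gene counted as hit if a site lay in its body plus 1 kb. Shares on X and per arm used exact binomial tests, differences between lists Fisher's exact test, and differences of medians or means 100000 resamples. Benjamini-Hochberg adjustment covered the 45 gene-list tests as a single family, the 20 annotation tests, and the 5 arms. The threshold was 0.05 and intervals are 95% Clopper-Pearson. Intervals and most tests treat entries as independent, which clustered sites are not, so intervals are too narrow and p-values can be too small. Of the gene symbols in the lists, Hop matched 2 genes, and vrille and HEXIM matched 0, and these were left out.

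The groups, the tests, the gene lists, most alternatives and the rule for named genes were fixed before the data were examined. The rule takes the 10 CO1 domains with the highest first value, every gene of the fixed lists with a site in its body plus 1 kb, and roX1 and roX2 in every list; each domain takes the longest coding gene that holds its midpoint, or otherwise the nearest gene. Genes named outside this rule, cic and caz among them, were chosen after their values were seen. The overlap of heat shock summits with CO1 domains, the closeness of higher to lower regions, their coding share, the CES density, the placement of CES summits inside CO1 domains and an adjustment of gene lists within each position list were added after the data were seen.

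Several planned tests were not run. Searches for GA repeats and heat shock elements need sequence, which was not used here. Position within the gene and distance to the start site need strand, so closeness to either gene end replaced the latter. Exon, intron and UTR classes and the size of change by chromosome were not analysed here. The tests of genes hit and of summits inside domains were tried on simulated placements of 467 summits, and the other tests were not simulated. With no effect, 5% of 100 simulated lists passed for genes and 3% for domains, and with 10 planted sites 100% passed. The gene trial used the 35 ecdysone and stress genes pooled, not the other lists. Simulated sites were placed independently over the same gene space that the tests assume, so false calls from clustered sites were not measured. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.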

Results

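The series measured where the long noncoding RNA roX2 lies on chromatin in Drosophila S2 cells, a cultured embryonic cell line. roX2 is an RNA component of the MSL complex, which raises transcription of the male X chromosome. An antisense oligonucleotide with a biotin tag captured the RNA from formaldehyde-fixed chromatin, and the DNA that came with it was sequenced. The labels describe 18 libraries, 15 from S2 cells and 3 from mouse embryonic fibroblasts. The analysis rests on 5 lists of positions. They are 246 CES summits tied to 2 mock libraries, 468 autosomal summits tied to 3 heat shock libraries (1 h at 37 °C), 392 regions called higher and 324 called lower after heat shock, and 429 domains of the library labelled CO1. CES is the usual abbreviation in this field for chromatin entry site, and the labels do not spell it out. Libraries treated with DRB or ecdysone, the library labelled CO2 and the Xist libraries are not analysed here. Sequencing depth is unknown, and the lists keep no value per library, so the tests below ask how sites are placed along the genome and say nothing of the spread between replicates.

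roX2 occupancy lay mainly on the X chromosome. Of 424 CO1 domains on the 6 chromosome arms, 313 were on X, which is 73.8% (95% Clopper-Pearson interval 69.4 to 77.9), against 17.6% by arm length (exact binomial test, two-sided, p = 1.2e-141). X domains covered 7.55 Mb, or 32.1% of X, while autosomal domains covered 0.73% of the autosomes. The median X domain was 15000 bp long and the median autosomal domain 4000 bp (permutation test, p = 2e-05, the smallest 100000 resamples can give). All 40 domains of 50 kb or more were on X. The authors' first value per domain, of unstated scale, had a median of 31.3 on X and 6 on the autosomes (permutation test, p = 2e-05).

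Among the 10 CO1 domains with the highest first value, 9 were on X. A domain with its midpoint in nej, which encodes a CBP-type histone acetyltransferase, spanned 9657501 to 9688000 with a value of 128 and extended past both ends of the gene. Other domains had their midpoint in Socs16D (125), RpL22 (120), CG44426 (112), Cyp4ae1 (99.8), Pgant7 (97.3) and CG17600 (96.5), and most of them also overlapped neighbouring genes. The highest value, 250, belonged to a 250 bp domain outside genes whose nearest gene was CG14621, and the next, 188, to a 3 kb domain assigned to CG15602. The autosomal member was a 250 bp domain in spok on 3R, with a value of 110.

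All 246 CES summits were on X (interval 98.5 to 100%; exact binomial p = 2.6e-186). Whether the authors restricted this list to X, or to occupied domains, is not stated. Each CES summit lay inside a CO1 domain. The lists come from different libraries, but a restriction to occupied domains would fix this overlap in advance. Random placement over X gene bodies plus 1 kb put 94.6 summits in domains on average (10000 draws, two-sided permutation p = 0.0002, the smallest the draws can give). Neighbouring CES summits were a median of 58.9 kb apart, against 61.7 kb in random placement (permutation p = 0.52).

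**Figure D1:**
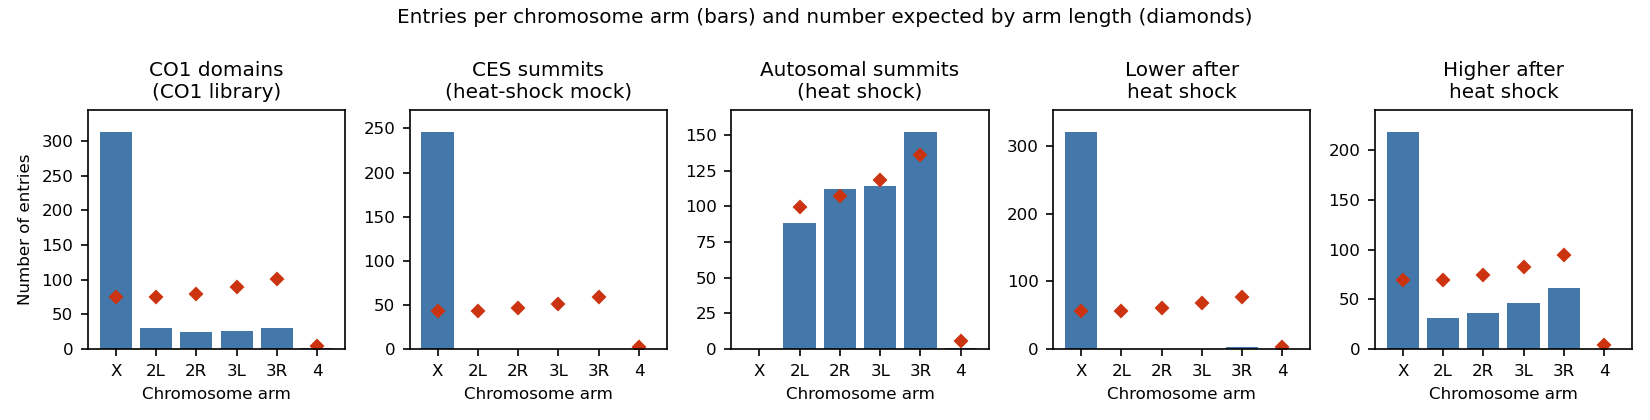
Number of entries per chromosome arm in each of the 5 lists (bars), with the number that arm length alone would give (diamonds; autosomal length only for the heat shock summits). X holds 313 of 424 CO1 domains, 246 of 246 CES summits, 321 of 324 lower regions and 218 of 392 higher regions.

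The genes for roX1 and roX2, the 2 RNAs of the MSL complex, each held a CES summit and lay in a CO1 domain. At roX1 (Release 6, X, 3857230 to 3862697) the summit was at 3861327 and the domain was 32.75 kb long, with a first value of 32.1. At roX2 (X, 11579065 to 11580432) the summit was at 11580221 and the domain was 74.5 kb long, with a first value of 65.8. A region called higher after heat shock covered the summit at both genes, from 3859001 to 3863700 and from 11577801 to 11581700. A region called lower began within each of these and ran on beyond it, from 3863201 to 3866400 at roX1 and from 11581201 to 11586000 at roX2. At mof, the acetyltransferase gene of the complex, a lower region ran from 5869501 to 5876600. Clamp, which encodes a DNA-binding protein that helps recruit the complex, held a heat shock summit at 22168780 on 2L. It was the only gene of the MSL list with such a summit, against 0.291 expected, and the list did not pass (permutation test). The complex genes msl-1, msl-2, msl-3 and mle had 0 entries in each list.

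**Figure D2:**
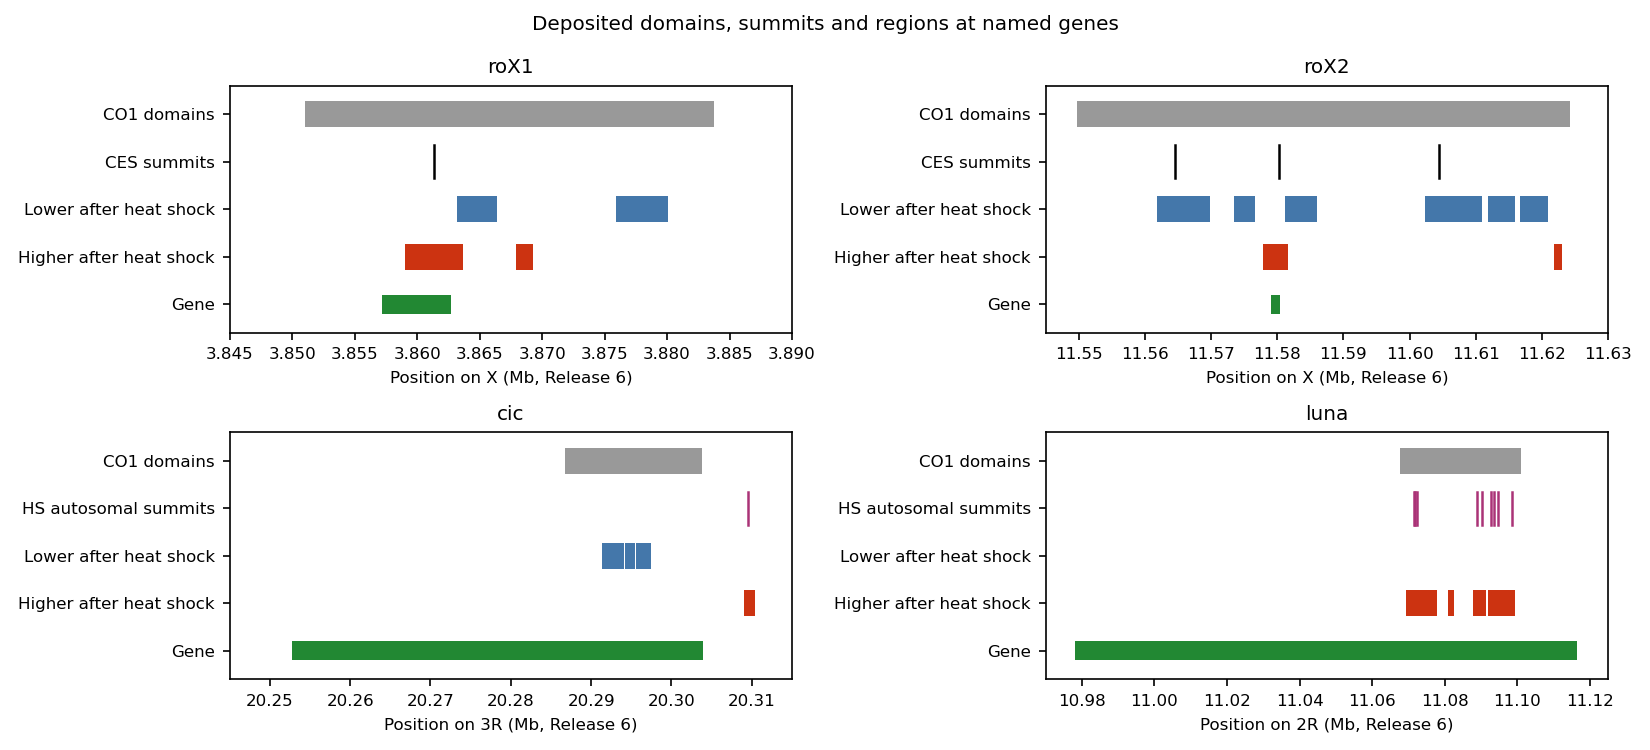
Maps of 4 genes drawn to scale, with position in Mb on the horizontal axis and rows for CO1 domains, summits, regions called lower or higher after heat shock, and the gene. Higher regions cover the CES summits of roX1 and roX2 with a lower region overlapping on the right, cic holds 3 lower regions side by side, and luna holds 9 heat shock summits.

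Regions called lower after heat shock were almost all on X, and regions called higher were divided between X and the autosomes. On X lay 321 of 324 lower regions (99.1%, interval 97.3 to 99.8) and 218 of 392 higher regions (55.6%, interval 50.5 to 60.6; Fisher's exact test, two-sided, p = 8.2e-51). A lower call needs signal without heat shock, and all 324 lower midpoints lay in CO1 domains. Those domains covered 32.1% of X and 0.73% of the autosomes, so this test cannot tell a loss particular to X from where roX2 lay beforehand. The 3 autosomal lower regions all lay in cic, which encodes a transcriptional repressor and is named after its values were seen, between 20291401 and 20297500 on 3R and inside a CO1 domain. They lay side by side, and with regions within 5 kb merged they formed 1 region. After that merging, 99.6% of lower and 53.6% of higher regions were on X (Fisher's exact test, p = 4e-42). The 174 autosomal higher regions fell on 2L (31), 2R (36), 3L (46) and 3R (61), with 0 on chromosome 4. Genes with the most higher regions, named after their values were seen, were Smr with 5, and InR and luna with 4 each.

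On X, higher regions were shorter than lower ones, with medians of 2450 bp (n = 218) and 5100 bp (n = 321; permutation p = 2e-05). A mean of 80.3% of each higher region lay in protein-coding gene bodies, against 95.9% of each lower region (permutation p = 2e-05). This comparison was added after the data were seen. Of 2197 coding genes on X, 179 held the midpoint of a higher region, 317 that of a lower region and 45 both, among them mys, nej, Smr and caz, the last 2 chosen after the values were seen.

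Regions called higher held 35 CES summits and regions called lower 65, while 146 were in neither. Placement over X gene space gave 7.93 and 24.6 (permutation p = 0.0002 for both), but all CES summits, all lower midpoints and 96.8% of higher X midpoints lay in CO1 domains. Placement inside the X CO1 domains, added after the data were seen, gave 20.0 for higher regions (permutation p = 0.0016) and 62.1 for lower regions (permutation p = 0.723), so the excess in lower regions was lost. The CES list and the changed regions share the mock libraries. The planned comparison of the 2 kinds found a CES summit in 65 of 321 lower X regions (20.2%) and 35 of 218 higher X regions (16.1%; odds ratio 1.33, Fisher's exact test, p = 0.259). With summits within 1 kb also counted, the odds ratio was 1.76 (Fisher's exact test, p = 0.00792). Computed afterwards per length, higher regions held 55.8 CES summits per Mb and lower regions 34.0 (ratio 1.64, exact binomial p = 0.0203), a difference lost when 1 kb was added around each region (ratio 1.07, p = 0.772).

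Heat shock summits lay on all 5 autosomal arms and several genes held many of them. Of 467 on the arms, 88 were on 2L, 112 on 2R, 114 on 3L, 152 on 3R and 1 on chromosome 4, where length gave 5.59. No arm passed against its share of length (exact binomial tests, adjusted p from 0.256 to 0.633; 0 arms before adjustment, chromosome 4 having p = 0.0512). Against gene body length, chromosome 4 had 6.59 expected (exact binomial p = 0.0176, adjusted p = 0.0879). luna, which encodes a zinc finger transcription factor, held 9 between 11071488 and 11098495 on 2R. Tm1 (tropomyosin), shep and the very long gene Myo81F (1966 kb) held 6 each, and the hormone receptor gene Eip75B, the insulin receptor gene InR, Nuak and SNF4Agamma 5 each. These genes were chosen after their counts were seen. In Myo81F, all summits but the one at 1909096 lay between 2085361 and 2089078 on 3R. On the arms, 268 genes held a summit and 27 held 3 or more. Neighbouring summits were a median of 83.2 kb apart, against 151 kb in random placement (permutation p = 0.0002). With summits within 5 kb merged, the 349 that remained were a median of 170 kb apart, against 202 kb (permutation p = 0.0046).

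Higher regions contained 237 of the 467 heat shock summits (50.7%, interval 46.1 to 55.4), against 1.92 expected (permutation p = 0.0002). These lists share the heat shock libraries, so their overlap is partly built in. Lower regions contained 0, which allows a share of up to 0.787%, but only 0.032 were expected, so this count is uninformative. CO1 domains, from a library with no heat shock label, contained 78 (16.7%, interval 13.4 to 20.4) against 3.60 expected (permutation p = 0.0002), a comparison added after the data were seen. The luna summits lay in a single CO1 domain of 33.25 kb. The Myo81F summits between 2085361 and 2089078 lay in a single CO1 domain of 4 kb with a first value of 64.3.

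Of 14 autosomal genes in the cytoskeleton and housekeeping list, 4 held a heat shock summit, against 0.524 expected (permutation test by random placement, adjusted p = 0.036). They were eEF1alpha1 and eIF4A, which encode translation factors, and chic and tsr, which encode the actin regulators profilin and cofilin. Of the same list over all arms, 4 of 17 held the midpoint of a higher region, namely Act5C, eEF1alpha1, eIF4A and Moe (0.556 expected, permutation test, adjusted p = 0.036). chic and eIF4A are neighbours on 2L, so they are not independent. With genes extended by 5 kb, the heat shock summit call was lost (5 genes, permutation test, adjusted p = 0.0607).

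Of 92 ribosomal protein genes, 6 had a higher midpoint in the gene body plus 1 kb, namely RpL22, RpS15Aa, RpS19a, RpS5a, RpL31 and RpL23 (1.16 expected, permutation test, adjusted p = 0.036). A CO1 domain midpoint lay in the same span of 7, namely RpL22, RpL7A, RpL17, RpL37-1, RpS5a, RpL31 and RpS7 (1.19 expected, permutation test, adjusted p = 0.027). X domains had a median length of 15000 bp, so a midpoint marks only some of the genes that a domain covers. The call on higher midpoints was lost with genes extended by 5 kb (7 genes, permutation test, adjusted p = 0.295), and the CO1 call with gene bodies alone (3 genes, permutation test, adjusted p = 0.251). No other combination of the 9 gene lists with the 5 position lists passed (Benjamini-Hochberg over 45 permutation tests). Random placement in these tests was even over gene bodies plus 1 kb, while all 5 lists favoured positions near gene ends. Of higher midpoints, 60.5% lay within 1 kb of a gene end, against 27.4% in uniform placement. Such positions fill most of a short gene, and length matching was not run for these lists. The calls therefore cannot tell a preference for a gene group from one for gene ends.

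Heat-inducible genes held 0 heat shock summits among 20 genes, 0 higher midpoints and 0 CO1 midpoints. Only 0.598 genes were expected to hold a summit, so this count is uninformative. The nearest summit was 1.676 kb from Hsp83, and the median distance over the list was 36.9 kb. Stress and early response genes with a summit in the gene body plus 1 kb were puc, kay, Xrp1, chrb and scyl (5 of 17, 1.25 expected, permutation test, adjusted p = 0.0765). Ecdysone response genes with a summit there were Eip74EF, Eip75B, EcR, Hr39, ftz-f1 and vri (6 of 14, 2.70 expected, permutation test, adjusted p = 0.254). Neither list passed the planned adjustment. In settings added after the data were seen, the stress list passed under uniform placement (permutation test, adjusted p = 0.027) and with adjustment over the 9 lists of these summits alone (adjusted p = 0.0459, permutation test). Among other chaperone genes, higher midpoints lay in Ubi-p5E, CCT2 and CCT6 and within 1 kb of Cdc37 (4 of 33, permutation test, adjusted p = 0.054). Heat shock summits lay in p23 and mrj (permutation test, adjusted p = 0.971). The MSL list had roX1 and roX2 among CES summits (2 of 3, permutation test, adjusted p = 0.13). Trl, vkg and the ribosomal protein genes RpL31, RpL23 and RpS28a also had heat shock summits in the gene body plus 1 kb, in lists with adjusted p of 0.883 or more (permutation tests). In combinations that did not pass, further list members had sites in the gene body plus 1 kb. Those with a higher midpoint there were roX1, roX2, Eip75B, ftz-f1, usp, puc, kay, scyl, His3.3B, Trl, Set2 and mys. Those with a lower midpoint there were mof, mys, Spt6 and Set2. Members with a CES summit there were Ubi-p5E, Moe, mys, Set2 and RpL22, and those with a CO1 midpoint were CCT6, Moe, vkg and Set2.

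**Figure D3:**
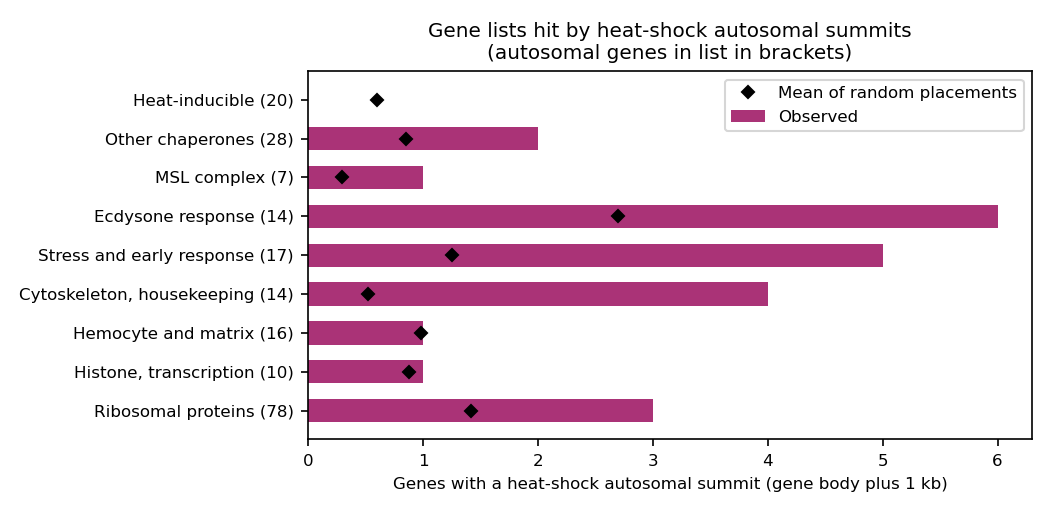
Number of genes in each list with a heat shock autosomal summit in the gene body plus 1 kb (bars), and the mean of 10000 random placements (diamonds); the number of autosomal genes per list is in brackets. The cytoskeleton and housekeeping list (4 of 14, 0.524 expected) is the only one here that passed adjustment.

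All 5 lists favoured protein-coding gene bodies, which held 89.8% of CES summits, 82.0% of heat shock summits, 82.1% of higher midpoints, 96.6% of lower midpoints and 81.6% of CO1 midpoints. They also favoured positions within 1 kb of either end of a gene, with 57.7% of CES summits, 44.1% of heat shock summits, 60.5% of higher midpoints, 38.6% of lower midpoints and 39.4% of CO1 midpoints. Uniform placement gave 66.7 to 70.7% for gene bodies and 26.3 to 29.0% for gene ends. Of 20 permutation tests over classes and lists, 16 passed (Benjamini-Hochberg), these 10 among them with adjusted p = 0.00027. At 250 bp the gene-end share of heat shock summits was 13.9% and that of lower midpoints 11.7%, and neither passed (permutation tests, adjusted p = 0.051 and 0.20).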

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

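The CO1 list holds 4 domains on the Y chromosome, which no comparison above used. They drew attention because their number is above a fixed limit of 3. No number expected for Y was computed, so whether 4 is more than expected is unknown. The 4 domains span 1 to 9250, 1642501 to 1642750, 2872001 to 2872250 and 3267751 to 3268500, with first values of 7.45, 33.2, 18 and 27.5. No technical or biological explanation was tested for them.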

How the results depend on the processing

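Across 32 results and 109 alternative settings, 98 settings left the direction and the side of the threshold as they were, or the count within 1.5 times; 4 ended a call, 4 brought one, 2 moved a value and 1 turned a direction. A count of passing tests enters this tally as a single result, so calls gained or lost within a count are not in it and stand below. Some settings were added after the data were seen. The X share of CO1 domains was 90.4% by covered length, a value without a test. The odds ratio for CES summits in lower against higher X regions passed with summits within 500 bp (1.68, Fisher's exact p = 0.0247) and within 1 kb (1.76, p = 0.00792). The excess of CES summits in lower regions was lost with placement inside X CO1 domains (65 against 62.1, permutation p = 0.723). The ratio of CES density fell to 1.07 within 1 kb (exact binomial p = 0.772). Of the gene-list combinations, 4 passed in the main setting, 2 with genes extended by 5 kb, 3 with gene bodies alone, 6 under uniform placement, 4 by any overlap and 6 with adjustment within each position list, the last 3 settings being added. The cytoskeleton call on higher midpoints passed in each of these. That list's call on heat shock summits was lost at 5 kb (5 genes, permutation, adjusted p = 0.0607), the ribosomal call on higher regions at 5 kb (adjusted p = 0.295) and by any overlap (adjusted p = 0.0645), and the ribosomal CO1 call with gene bodies alone (adjusted p = 0.251; permutation tests). Under uniform placement the stress list passed for heat shock summits (5 genes, permutation, adjusted p = 0.027) and the other chaperones for higher midpoints (adjusted p = 0.0234), the latter also by any overlap (adjusted p = 0.0315). Adjustment within each position list passed the same pair (permutation, adjusted p = 0.0459 and 0.018). Annotation tests passed in 16 of 20 cases, and in 14 at 250 bp, where the gene-end calls for heat shock summits and lower midpoints were lost. For higher regions near lower ones, overlap alone did not pass (39 regions, permutation p = 0.104), and placement inside X CO1 domains turned the direction, with 55 observed below its mean of 82.6. The cause was not tested except where the wider window itself adds sites or genes. Gene lists were tested in 45 combinations under 5 settings, with the further adjustment, and annotation classes in 20 under 2. Alternatives that keep the higher-valued part of a list were not run for the 4 lists without values, nor were those for sequence, strand or size of change. No paired analysis was possible because the lists hold no column per library, although heat shock and mock share replicate numbers 1 and 2. Depth is unknown, so what depth limits cannot be stated.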

Other observations

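The patterns below were found and tested on the same data, so what follows are hypotheses. The test on short domains and the test with lower regions closed to higher ones were chosen only after the result was seen. The other predictions were written before their tests ran, but after the overlaps, distances, list hits and the maps of roX1 and roX2 that prompted them had been seen. No biological explanation was tested through replicates, since the lists hold none.

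Of 467 autosomal heat shock summits, 78 (16.7%) lay where the CO1 library had a domain, more than the 3.60 expected, while most lay outside domains. Moving each summit at random by up to 20 kb left a mean of 24.7 in domains (permutation p = 0.0002). Such a move can carry a summit out of a short gene such as Uba1 (5.04 kb) and moves clustered summits separately. It therefore cannot decide whether both lists merely favour the same genes, which stays open. Summits inside domains lay in higher regions more often than the others (71.8% against 46.5%, odds ratio 2.93, Fisher's exact p = 5.9e-05). These 78 summits cluster in 47 domains, 9 of them in the luna domain, so this p is too small. The direction is the reverse of the one that sites already occupied, and therefore not called higher, would give, but its spread over domains was not tested. Short domains, as a collapsed repeat might give, made up 8.51% of the 47 domains with a summit (interval 2.37 to 20.4) and 16.2% of all autosomal domains, and domains longer than 1 kb held 74 of the 78 summits against 3.64 expected (permutation p = 0.0002), which argues against short domains as the whole cause although the interval just passes the 20% limit set for the share. A candidate explanation is weak autosomal occupancy that heat shock raises, which was not tested, since the lists hold no size of change. Longer repeats and fragments captured directly by the oligonucleotide, neither tested here, also stay open. The test of short domains did not cover the 4 kb domain in Myo81F, whose first value was 64.3 against an autosomal median of 6. The CO1 list also holds a mitochondrial domain from 1 to 19500 with a first value of 17.6. A domain in that list thus need not mark roX2 on nuclear chromatin.

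On X, 55 of 218 higher regions lay within 500 bp of a lower region, against 32.9 in random placement over gene space (1000 draws, permutation p = 0.002, the smallest they can give), a call that overlap alone ended (39 against 30.2, permutation p = 0.104). Placement inside the X CO1 domains gave 82.6, more than observed, but both placements let regions overlap deeply while real overlaps reached at most 800 bp, so neither decides. A further placement, devised after that outcome, took its overlap limit from the observed regions and gave 25.3 (permutation p = 0.002), so the answer turns on how overlap is treated and shared domains stay open. Higher regions with a CES summit were near a lower region in 11 of 35 cases and the others in 44 of 183 (odds ratio 1.45, Fisher's exact p = 0.397), so a rise at entry sites with falling flanks, as roX1 and roX2 may show, is neither excluded nor borne out. How the authors' calling splits neighbouring windows is not given in the sources used here and stays open.

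Ecdysone and stress genes are long, with a median of 17.0 kb against 2.10 kb for coding genes, which could explain why summits fall in them. Random genes of the same arms matched on length were hit 2.91 times on average, against 11 of 31 list genes (permutation p = 0.0002, the smallest the draws can give). This pools 2 of the 9 lists, picked after their hits were seen, and neither passed the planned adjustment (permutation, adjusted p = 0.0765 and 0.254), so this test cannot decide on genes chosen for the pattern. Gene length stays open, as does expression level, which was not analysed here.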
